A study of Mus musculus with 4 samples.

How the data were processed

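The data were 4 ChIP-seq peak lists from iKPC mouse pancreatic cancer cells after doxycycline withdrawal and TGFβ treatment, 1 for each of the antibodies to NFAT5, SMAD2, SMAD3 and SMAD4. Grouping followed the antibody named in the labels. With 1 library per antibody there were no replicates, no control library was analysed here, and no comparison between antibodies was tested.

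The submitters' processing notes name Trimmomatic 0.38, FastQC, Bowtie2, SAMtools 1.9, Picard 2.18.26, MACS2 2.1.2 and deepTools, without saying what each step used, and name both the GRCm38 and the hg38 build. The peak caller's threshold and whether an input library was used are not given in the sources used here. The authors deposited each list as positions with a running number and a score, and the score was 0 in every row, so peaks could not be ranked or filtered by strength. The deposited start and end coordinates are positions, a unit outside the usual measurement scales, and gave each peak's width. Width grows with enrichment, but also with the caller's settings and the fragment length, so it served to rank peaks within a list. The ratio of NFAT5 to SMAD width at a gene depends on both libraries and was set only against the same ratio at other genes. No read counts were in the files, so the depth of each library was unknown. A deeper library yields more and wider peaks from the same binding, so the different list lengths are not measures of binding, and a site missing from the shorter NFAT5 list is not shown to be unbound. Fragments counted after PCR are not independent molecules, and intervals cover counting error only.

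The peaks were read as GRCm38. This was checked by counting peaks within 1 kb of a coding gene end at the given positions (27.9% for NFAT5) and after shifting all positions by 20 or 100 kb (5.47% to 6.02%). Genes came from a RefSeq table for GRCm38.p6 with 49943 genes, of which 21887 were protein-coding. It gave the gene's span and no strand, so the planned distance to a transcription start was replaced by the distance to the nearer end of the span, and the number of transcripts replaced the number of starts for matching gene lists. No genome sequence was used here, so the planned search for binding motifs was not run, and introns and exons were not told apart.

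A pair of peaks was called shared when they overlapped by at least 1 bp. Shares have exact 95% Clopper-Pearson intervals and were set beside 100 placements of the peaks at random positions of the same chromosome, and for NFAT5 also 100 placements at random coding gene ends with the peak's own offset. Merged regions are the unions of overlapping peaks of the 4 lists. Each SMAD list was also split into 5 equal parts by width. A gene was bound when a peak midpoint lay within 5 kb of either end of its span. The 15 gene lists were fixed before the data were examined, and all of their 247 entries (242 different genes) were found in the table. Some entries are neighbours or appear in more than 1 list. Each list's count was set against 10000 random lists of coding genes matched on the number of transcripts (1, 2, 3 to 4, 5 to 8, over 8), and also against genes that all 3 SMADs bound. Members of cell-type lists are background knowledge, and no expression data were analysed here.

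Genes were named by a rule fixed before the data were examined: 6 genes always; up to 4 members of each list with NFAT5 and a SMAD; the 10 genes with the strongest NFAT5 peak shared with all 3 SMADs; and for each SMAD, and for NFAT5 peaks without SMADs, the 5 strongest. Because the score was 0 throughout, strength was replaced by width, and a peak was assigned to the coding gene with the nearest end, if within 5 kb. Other list members named in the text were chosen after their values were seen.

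Alternatives were an overlap of at least 50% of the shorter peak, midpoints within 200 bp, gene-end windows of 3 kb, gene windows of 1 and 20 kb and coding genes alone. Thresholds by score, intended before the data were examined, could not be made, and thresholds by width were added after seeing the data: peaks of at least 400 bp, the widest 50% of each list, and lists of equal length holding the 9071 widest peaks. The autosomes alone and the gene span plus 5 kb were also added. The scripts were tested on simulated data. With peaks placed to give overlap shares of 20.0%, 49.99% and 89.99% for 9071 peaks, the same shares were recovered. Unrelated lists of 20 genes had a mean percentile of 49.8, and 93.0% of lists of 20 genes bound at 70% against 30% of all genes lay above the 97.5th percentile of random lists. These simulations checked the code. They do not give the power for the lists analysed here, since NFAT5 was at 19.9% of coding genes and the simulated genes were independent. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.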

Results

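The binding sites of 4 transcription factors were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which DNA crosslinked to a protein is recovered with an antibody and sequenced. The factors were NFAT5, known for switching on genes of the response to hypertonic stress, and SMAD2, SMAD3 and SMAD4, which carry the TGFβ signal to the nucleus. The cells were iKPC cells, a mouse pancreatic cancer line with a doxycycline-inducible mutant Kras allele and a conditional Trp53 allele. They were grown with doxycycline at 1 µg/ml, and doxycycline was then withdrawn with TGFβ given at 0.5 ng/ml for 3 days. Each antibody had 1 library, so no difference between antibodies could be tested against replicates, and no control library and no untreated or doxycycline-treated cells were analysed here. The files gave peak positions in the mouse genome (GRCm38) without read counts, so the depth of each library was unknown. The NFAT5 list held 9071 peaks with a median width of 381 bp. The SMAD2, SMAD3 and SMAD4 lists held 36236, 27552 and 31062 peaks, with median widths of 392, 405 and 455 bp. Intervals below are exact 95% Clopper-Pearson intervals and cover counting error only.

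The design asked which genes carried NFAT5 together with the SMADs. Most NFAT5 peaks lay where all 3 SMADs also had a peak, among them peaks at Serpine1, which encodes the plasminogen activator inhibitor PAI-1, at Skil, a feedback repressor of SMAD signalling, at Tgfb1 and at S100a4, which encodes a calcium-binding protein of motile cells. Of the 9071 NFAT5 peaks, 7652 overlapped a peak of each of SMAD2, SMAD3 and SMAD4 by at least 1 bp, which was 84.4% (interval 83.6 to 85.1). At least 1 SMAD was present at 8810 NFAT5 peaks, or 97.1% (96.8 to 97.5). When the NFAT5 peaks were placed at random on their chromosomes 100 times, a mean of 0.827% and at most 1.04% overlapped all 3 SMADs. When they were moved to random gene ends at their own distance from the end, the mean was 3.81% and the highest share 4.24%. The shared peaks were nearly centred on each other, with a median distance between midpoints of 67 bp to SMAD2, 67 bp to SMAD3 and 69 bp to SMAD4. The SMAD lists were 3.04 to 3.99 times as long as the NFAT5 list, and the converse shares were smaller. NFAT5 was present at 23.1% of SMAD2 peaks, 29.3% of SMAD3 peaks and 27.0% of SMAD4 peaks. The value depended on list length: with each list reduced to its 9071 widest peaks, a comparison added after seeing the data, 35.3% of NFAT5 peaks overlapped all 3 SMADs. Each list came from a separate immunoprecipitation, so a shared position did not show that the proteins sat on the same DNA molecule.

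**Figure D1:**
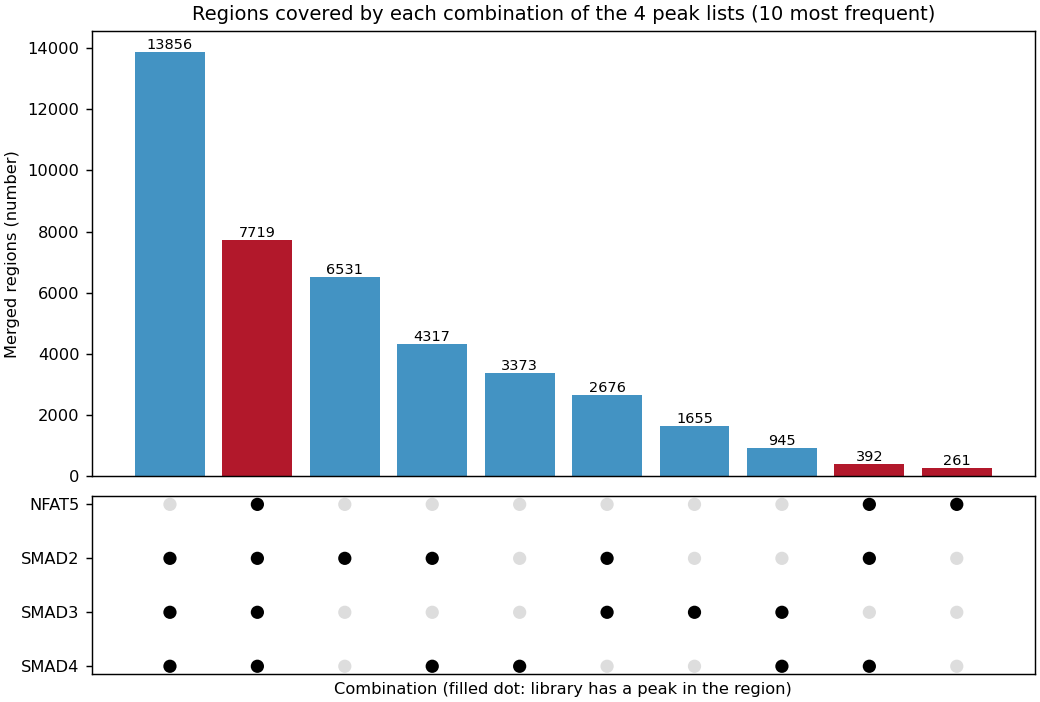
Number of merged regions (y axis) for the 10 most frequent combinations of the 4 peak lists, with filled dots marking the libraries that had a peak in the region and red bars marking combinations with NFAT5. Regions with all 3 SMADs and no NFAT5 numbered 13856, regions with all 4 libraries 7719 and regions with NFAT5 alone 261.

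Merging the 4 lists gave 42355 regions. The 3 SMADs shared 21575 of these regions (50.9%), and NFAT5 was present at 35.8% of the shared ones. Regions with SMAD2 alone numbered 6531 and those with SMAD4 alone 3373. NFAT5 was found more often at wide SMAD peaks. With the SMAD4 peaks in 5 equal parts by width, 5.75% of the narrowest part (median 273 bp) overlapped NFAT5 (5.18 to 6.35), and 55.3% of the widest part (median 848 bp) did (54.1 to 56.6). The same shares ran from 4.08% to 55.2% for SMAD2 and from 7.60% to 58.6% for SMAD3. A wider peak also offers more length to overlap. NFAT5 presence at sites of all 3 SMADs also differed between chromosomes, from 20.9% (17.6 to 24.4) on chromosome 14 to 44.1% (41.8 to 46.5) on chromosome 3 among the autosomes, and it was 13.8% (9.04 to 19.8) on the X chromosome.

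**Figure D2:**
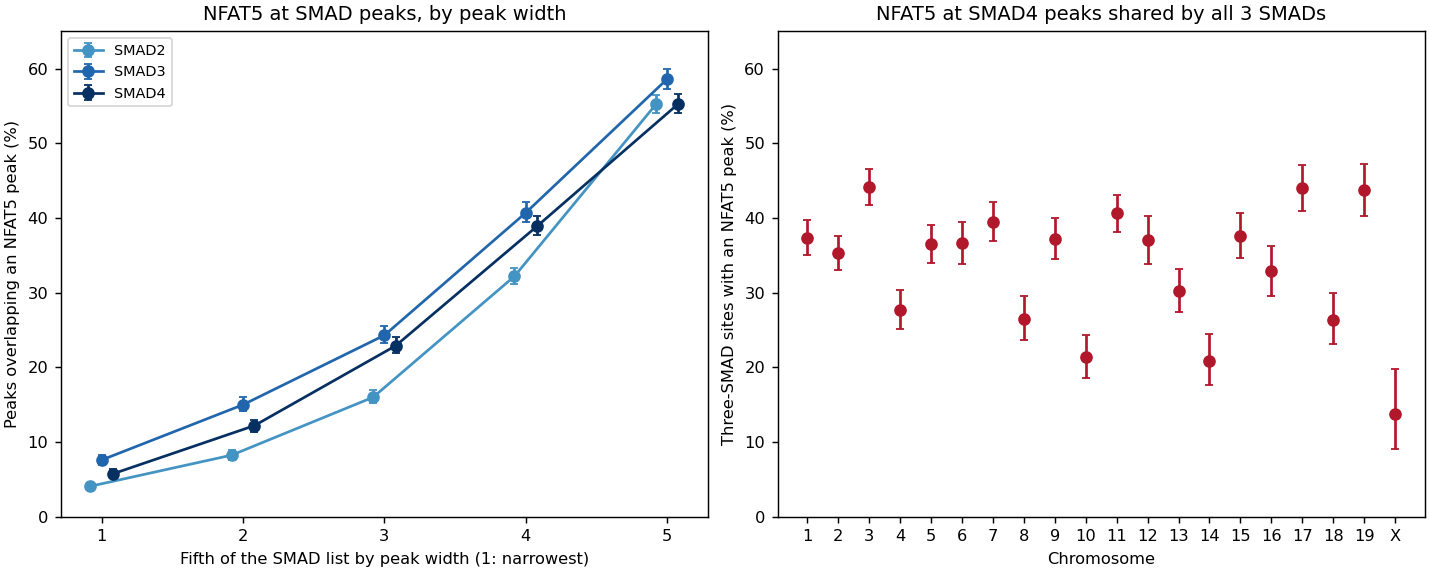
Left, share of SMAD peaks that overlapped an NFAT5 peak (%) in 5 equal parts of the SMAD list by peak width; right, share of SMAD4 peaks overlapped by SMAD2 and SMAD3 that also overlapped NFAT5 (%), by chromosome. Points are shares and bars exact 95% intervals. The SMAD4 share rose from 5.75% to 55.3% with width, and the autosomes ran from 20.9% on chromosome 14 to 44.1% on chromosome 3.

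At the level of genes, a gene was called bound when a peak midpoint lay within 5 kb of either end of its annotated span. Of 21887 protein-coding genes, 4346 (19.9%) were bound in the NFAT5 library, 10779 with SMAD2, 9672 with SMAD3 and 10631 with SMAD4. All 4 libraries had a peak at 3835 genes, which were 88.2% of the NFAT5-bound genes and 17.5% of all genes. At 3455 genes, 1 and the same NFAT5 peak overlapped all 3 SMADs. NFAT5 was present at 46.1% of the 8318 genes bound by all 3 SMADs. Within 1 kb of a gene end, 2393 genes had all 4 libraries. Below, a gene without a peak is one without a peak midpoint within 5 kb of its ends, unless its span is named.

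The genes of the factors themselves differed. Nfat5 (chromosome 8, 107293435 to 107379517) had a peak of every library across its lower-coordinate end, with the NFAT5 peak at 107293176 to 107293686. Smad2 and Smad4, both on chromosome 18, each had a SMAD2 and a SMAD4 peak at one end and no NFAT5 or SMAD3 peak. Smad3 had 2 peaks of each SMAD library near its ends and no NFAT5 peak there, while 5 NFAT5 peaks lay elsewhere in its span. Smad7 (chromosome 18, 75367365 to 75395935), the inhibitory SMAD that TGFβ induces, had 6 SMAD2, 7 SMAD3 and 6 SMAD4 peaks in its span or within 5 kb and no NFAT5 peak. NFAT5 presence was low on that chromosome, at 26.4% (23.1 to 30.0) of the sites shared by the SMADs. S100a4 (chromosome 3, 90603770 to 90606045) had 1 NFAT5 peak inside the gene, at 90604272 to 90604928, and it overlapped SMAD2 by 561 bp, SMAD3 by 583 bp and SMAD4 by 539 bp.

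**Figure D3:**
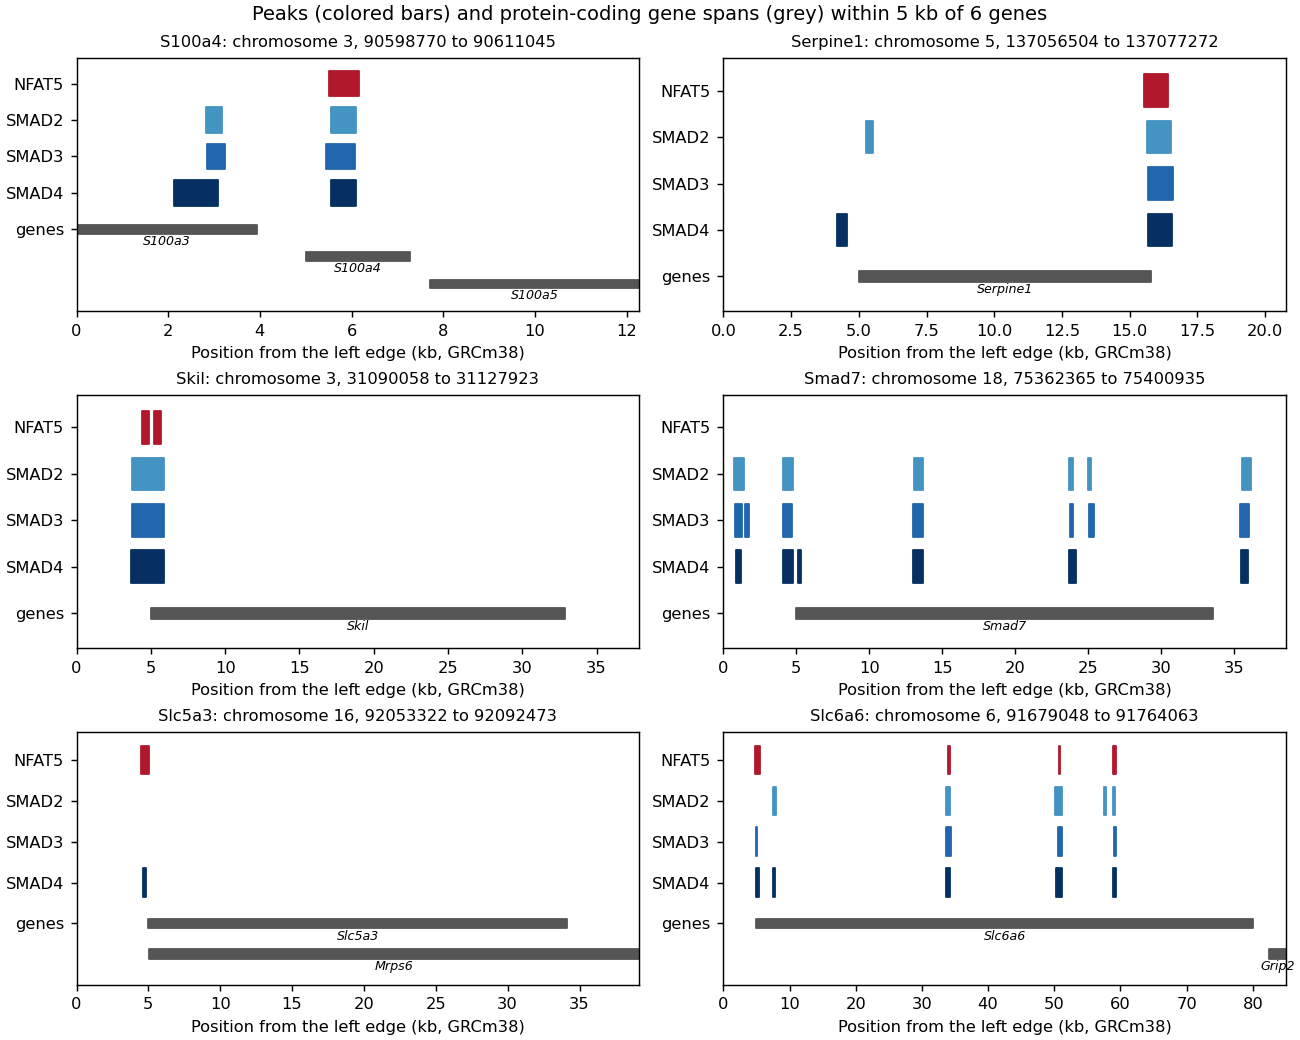
Maps of 6 genes with 5 kb on each side (x axis, kb from the left edge, GRCm38), with peaks of the 4 libraries as colored bars and protein-coding gene spans in grey. S100a4, Serpine1 and Skil had NFAT5 and SMAD peaks at the same place, Smad7 had 6 to 7 peaks of each SMAD library and no NFAT5 peak, and the NFAT5 peak of Slc5a3, 549 bp wide, overlapped a SMAD4 peak of 255 bp alone.

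Most TGFβ/SMAD target and feedback genes carried the SMADs, and NFAT5 was at 10 of them. Of the 26 genes, 23 had SMAD2, 23 SMAD3 and 22 SMAD4 peaks, and the 10 with NFAT5 peaks had all 3 SMADs too. These 10 were Bhlhe40, Cdkn1a, Id1, Id2, Ltbp3, Pmepa1, Serpine1, Skil, Smad6 and Tgfb1. The count of 10 lay at percentile 98.4 of 10000 random lists of coding genes, whose median was 5. Among genes that all 3 SMADs bound, 10 of 22 lay at percentile 48.7. Within 1 kb of a gene end the count was 4 (percentile 62.7), within 20 kb 15 (percentile 99.5), and with the widest 50% of each list, chosen after seeing the data, 8 (percentile 99.8). The NFAT5 peak of Serpine1 lay across the higher-coordinate end of the gene, on chromosome 5 at 137072047 to 137072933, and shared 780 bp with SMAD2, 753 bp with SMAD3 and 764 bp with SMAD4. That of Cdkn1a, which encodes the cell-cycle inhibitor p21, lay inside the gene on chromosome 17 at 29094506 to 29095718 and fell entirely within peaks of the 3 SMADs. At Tgfb1 the NFAT5 peak was 948 bp wide and at Ltbp3, which encodes a binding protein of latent TGFβ, 674 bp. Ski, Smurf1, Tgfbr1, Tgif1 and Junb were among the genes bound by all 3 SMADs without NFAT5 within 5 kb of their ends. Anywhere in the gene span or within 5 kb, a rule added after seeing the data, NFAT5 was at 15 of the 26 (percentile 100.0 after rounding). That count grows with gene length, on which the random lists were not matched.

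Receptors, ligands and SMADs of the TGFβ and BMP pathways were bound by NFAT5 at 5 of 17 genes, namely Acvr1, Bmpr2, Eng, Tgfb2 and Tgfb3 (percentile 79.2). SMAD2 and SMAD4 each bound 14 of these 17 genes (percentiles 99.4 and 99.5) and SMAD3 bound 8 (percentile 50). Among EMT and mesenchymal regulators, NFAT5 was at 4 of 17 genes (percentile 68.6), which were Vim, S100a4, Itga5 and Mmp14. The NFAT5 peak of Vim, the gene of the intermediate filament vimentin, was 1005 bp wide and reached the lower-coordinate end of the gene. Snai1, Zeb1 and Fn1 had peaks of all 3 SMADs and no NFAT5 peak, and Twist2, Zeb2, Prrx1, Mmp2, Cdh11 and Sox4 had no peak of any library within 5 kb of their ends. Of 18 extracellular matrix genes, 5 had NFAT5 (percentile 78.5), namely Col1a1, Itgav, Lamc2, Sparc and Thbs1. SMAD2 was at 14 of the 18 (percentile 98.9), SMAD4 at 13 (percentile 97.2) and SMAD3 at 7 (percentile 29.4). Col4a1, Col4a2, Loxl2, Itgb5 and Tnc had SMAD2 and SMAD4 peaks without a SMAD3 peak. At both Col4a1 and Col4a2 the SMAD2 peak was 395 bp and the SMAD4 peak 550 bp wide, so these genes may have counted the same peaks. Counting peaks anywhere in the gene span or within 5 kb, a rule added after seeing the data, NFAT5 was at 8 EMT genes (percentile 98.1) and 10 matrix genes (percentile 99.6). Such counts grow with gene length, on which the random lists were not matched.

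Genes known as NFAT5 targets in osmotic stress were bound by NFAT5 at 7 of 15 (percentile 99.3), and among those that all 3 SMADs bound at 5 of 7 (percentile 89.3). The 7 were Nfat5 itself, Slc5a3 and Slc6a6, which encode the myo-inositol and taurine transporters, Slc38a2, which encodes an amino acid transporter, and the heat-shock protein genes Hspa1a, Hspa1b and Hspa4l. In the SMAD libraries 8 or 9 of the 15 genes were bound, at percentiles of 79.9 to 84.5. The NFAT5 peak of Slc5a3 on chromosome 16, at 92057793 to 92058341, overlapped SMAD4 and neither SMAD2 nor SMAD3. At the lower-coordinate end of Slc6a6 on chromosome 6, the NFAT5 peak at 91683853 to 91684610 was 758 bp wide. It shared 461 bp with SMAD4, 238 bp with SMAD3 and none with SMAD2. Elsewhere in the span of Slc6a6, NFAT5 peaks at 91712932 to 91713360, 91729742 to 91729989 and 91737931 to 91738316 each overlapped all 3 SMADs. At Hspa1b the NFAT5 peak of 841 bp coincided with SMAD peaks of 763 to 907 bp. Akr1b3, which encodes aldose reductase, had SMAD peaks and no NFAT5 peak, and Slc6a12, Slc14a2, Sgk1, Vegfc and Nos2 had no peak of any library within 5 kb of their ends. Anywhere in the gene span or within 5 kb, a rule added after seeing the data, NFAT5 was at 9 of the 15 (percentile 99.9). This count, too, grows with gene length, on which the random lists were not matched.

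**Figure D4:**
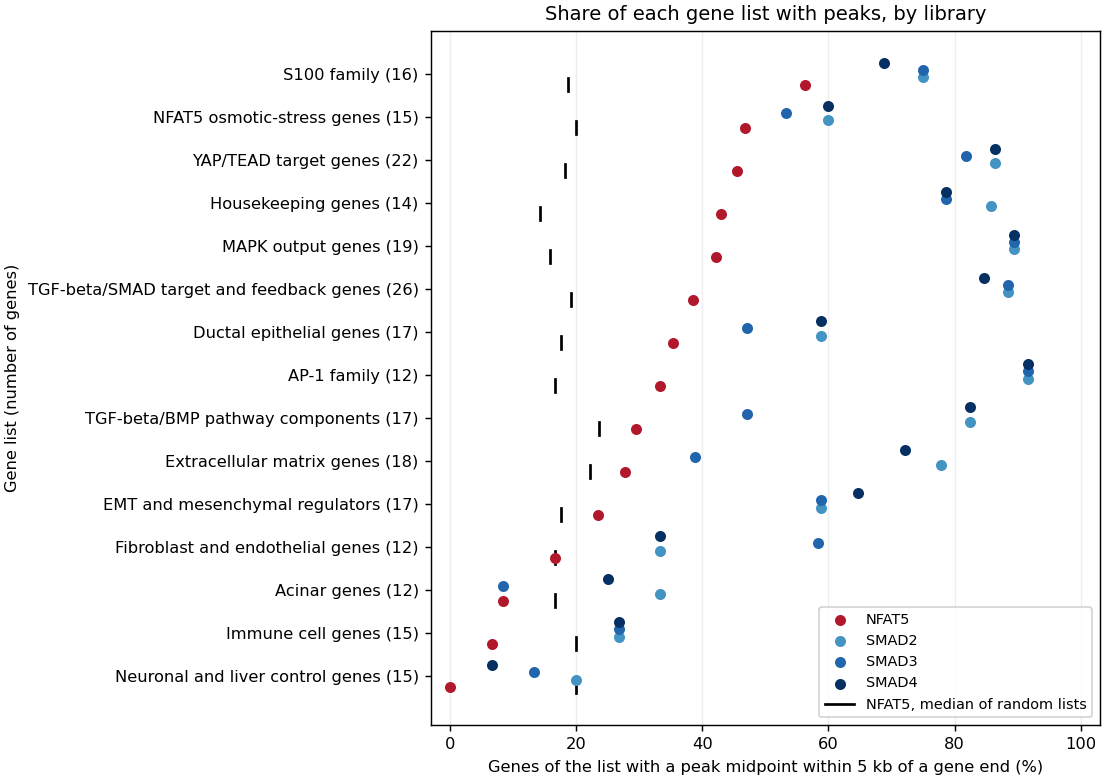
Share of the genes of each of 15 lists with a peak midpoint within 5 kb of a gene end (%), for the 4 libraries, with the number of genes in brackets and the NFAT5 median of random lists as a black line. NFAT5 was at 9 of 16 S100 genes and 7 of 15 osmotic-stress genes, at 6 of 14 housekeeping genes, and at 0 of 15 neuronal and liver genes.

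Of the 15 lists, the S100 family of calcium-binding proteins had the highest share of NFAT5-bound members, 9 of 16, at percentile 100.0 after rounding. Among its 11 members that all 3 SMADs bound, 9 had NFAT5 (percentile 99.0). The 9 genes rested on 7 distinct NFAT5 peaks, since S100a3, S100a4 and S100a5 lie close together and counted the same peak, S100a5 and S100a6 also shared a peak, and so did S100a1 and S100a13. Of the bound genes, 8 lie on chromosome 3, where NFAT5 was at 44.1% of the sites shared by the SMADs. S100a8 and S100a9, the myeloid members at the far side of the cluster, had no peak of any library within 5 kb of their ends, and S100a10 and S100a14 had SMAD peaks without NFAT5.

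Targets of other pathways also carried NFAT5. It was at 10 of 22 YAP/TEAD target genes (percentile 99.7; among those with all 3 SMADs 9 of 18, percentile 63.8), with wide peaks at Amotl2 (1038 bp), Ptpn14 (769 bp) and Nuak2 (676 bp). It was at 8 of 19 MAPK output genes (percentile 99.3; with all 3 SMADs 8 of 14, percentile 80.2), among them Spred1, Spry1, Ccnd1 and Fosl1, where each SMAD bound 17 of 19. Of the 12 AP-1 family genes, 4 had NFAT5 (percentile 92.6), namely Fos, Fosl1, Jun and Jund, and 11 had each SMAD. Of 17 ductal epithelial genes, 6 had NFAT5 (percentile 94.9), namely the keratin genes Krt8, Krt18 and Krt19, the mucin gene Muc1, Cldn4 and Elf3, while Cdh1 and Epcam had no peak of any library within 5 kb of their ends. Anywhere in the gene span or within 5 kb, a rule added after seeing the data, NFAT5 was at 10 ductal genes (percentile 99.9). Here again the count grows with gene length, on which the random lists were not matched. Within 1 kb of a gene end NFAT5 was at 4 S100 genes (percentile 91.4), 6 YAP/TEAD targets (percentile 95.9), 4 MAPK output genes (percentile 84.5), 2 AP-1 genes (percentile 72.3), 4 ductal genes (percentile 89.3) and 5 osmotic-stress genes (percentile 98.0). Within 20 kb these 6 lists had, in the same order, 11, 16, 10, 8, 10 and 9 genes with NFAT5 (percentiles 99.9, 100.0, 96.9, 99.6, 98.9 and 98.6). With the widest 50% of each list, chosen after seeing the data, it was at 4 YAP/TEAD targets (percentile 86.6), 4 MAPK output genes (percentile 92.6), 4 AP-1 genes (percentile 99.1), 3 ductal genes (percentile 83.6), 6 osmotic-stress genes (percentile 99.8) and 6 S100 genes (percentile 99.8).

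Housekeeping genes were also bound above the random lists. NFAT5 was at 6 of 14 (percentile 99.0), which were Eef2, Hmbs, Ppia, Rplp0, Sdha and Ubc, and the SMADs were at 11 or 12 of 14. Among the housekeeping genes with all 3 SMADs, NFAT5 was at 6 of 10 (percentile 81.7). NFAT5 was at 5 housekeeping genes within 1 kb (percentile 99.2), 8 within 20 kb (percentile 99.1) and 2 with the widest 50% of each list (percentile 77.7). In lists of other cell types NFAT5 counts within 5 kb of a gene end were at or below the median of random lists. NFAT5 was at 1 of 15 immune cell genes (percentile 9.9), Cd79a, where the midpoint of its peak lay 2496 bp beyond the gene. It was at 1 of 12 acinar genes (percentile 26.7), Cela1, and at 2 of 12 fibroblast and endothelial genes (percentile 40.2), Kdr and Rgs5, where SMAD3 was at 7 of 12 (percentile 80.5) and SMAD2 and SMAD4 at 4 each. For the fibroblast and endothelial genes the NFAT5 count was 5 within 20 kb (percentile 69.6) and 5 with the gene span plus 5 kb (percentile 88.5). The span rule was added after seeing the data, and its counts grow with gene length. None of 15 neuronal and liver control genes had NFAT5 (percentile 1.4), and SMAD2, SMAD3 and SMAD4 were at 3, 2 and 1 of them. The SMADs were at 4 of 15 immune genes each. In the remaining lists that held such genes, NFAT5 among genes with all 3 SMADs lay at percentiles of 27.6 to 82.5. With 1 library per antibody, percentiles describe these libraries and carry no p-value.

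Among NFAT5 peaks within 5 kb of a coding gene end, the widest shared with all 3 SMADs lay near Msln, Gadd45g, Pdlim7, 4931408C20Rik, Hjurp, Cwc22, Tab1, Scx, Cdkn1a and 9130023H24Rik. The peak near Msln, which encodes the tumour antigen mesothelin, was on chromosome 17 at 25756202 to 25757723, 1522 bp wide with its midpoint 2584 bp beyond the gene, and SMAD2, SMAD3 and SMAD4 covered 1522, 1522 and 1472 bp of it. Near Gadd45g, a stress-response gene, the NFAT5 peak was 1450 bp wide, and in Pdlim7 it was 1416 bp wide. Tab1, which encodes a partner of the TGFβ-activated kinase TAK1, had an NFAT5 peak of 1242 bp inside the gene, and Scx, which encodes the tendon factor scleraxis, one of 1230 bp beside it. Repeat content at these genes was not checked.

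Among SMAD peaks within 5 kb of a coding gene end, Skil had one of the 5 widest in all 3 libraries, with peaks of 2196, 2128 and 2189 bp for SMAD2, SMAD3 and SMAD4. There 2 NFAT5 peaks, the wider of them 479 bp, lay inside the SMAD peaks, on chromosome 3. For SMAD2 the others were Akt3 (1910 bp), Ubb (1869 bp), Cnn3 (1811 bp) and Msln (1808 bp). For SMAD3 they were Pdgfb (1918 bp), Ptma (1890 bp), Elf2 (1822 bp) and 1700001C19Rik (1758 bp), and for SMAD4 Foxo1 (2707 bp), Cdkn1a (2306 bp), Tiparp (2258 bp) and Elf2 (2244 bp). Akt3, which encodes a kinase of the PI3K pathway, and Elf2 had no NFAT5 peak within 5 kb of their ends. At Foxo1 the NFAT5 peak was 239 bp wide.

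NFAT5 peaks without any SMAD peak were few and narrow, 261 in number (2.88%, 2.54 to 3.24) with a median width of 300 bp against 396 bp for those shared with all 3 SMADs. The widest near coding genes were at Calm2 (615 bp), Jun (612 bp), Idh2 (572 bp), Slc29a2 (554 bp) and Urb1 (526 bp). In Jun, which encodes a subunit of AP-1, the peak lay inside the gene on chromosome 4 at 95051164 to 95051775, with SMAD peaks just beyond the gene. Urb1 had no SMAD peak within 5 kb of its ends, which held for 28 NFAT5-bound genes.

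Among the SMADs, sharing was also extensive. Of the SMAD3 peaks, 89.4% overlapped SMAD2 (89.0 to 89.7) and 83.3% overlapped SMAD4 (82.8 to 83.7), and 85.0% of the SMAD4 peaks overlapped SMAD2 (84.6 to 85.4). Random placements gave means of 1.29% to 1.45% for these pairs. Median midpoint distances were 45 to 50 bp. With all lists at the 9071 widest peaks, the shares between SMADs were 65.3% to 67.2% and those of NFAT5 with each SMAD 52.4% to 53.0%. A gap between NFAT5 and the SMADs could not be tested against replicates.

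Peaks of all 4 libraries were concentrated near genes. Within 1 kb of an annotated gene end lay 33.4% of NFAT5 peaks (32.4 to 34.4), 25.4% of SMAD2 peaks (24.9 to 25.8), 28.8% of SMAD3 peaks (28.3 to 29.3) and 28.5% of SMAD4 peaks (28.0 to 29.0). Random placements gave 6.32% to 6.44%. The gene table had no strand, so the end with the transcription start was not known. More than 20 kb from any end of a coding gene lay 37.7% of NFAT5 and 46.0% of SMAD2 peaks.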

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

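The thresholds by width (at least 400 bp, widest 50%, equal length), the autosomes alone and the gene span plus 5 kb were chosen after seeing the data. Thresholds by score, and the motif search with its other windows and backgrounds, were not run, since the score was 0 throughout and no genome sequence was used here. Under each overlap rule and list threshold run, the share of NFAT5 peaks at all 3 SMADs stayed above the 4.24% that placements at gene ends reached with the full lists, and equal list length moved it most. The causes were not tested, except that shorter lists and narrower windows hold fewer peaks by construction. Unknown depth limits every missing site, in the NFAT5 list as in the SMAD lists.

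With peaks of at least 400 bp, 4087 NFAT5, 17608 SMAD2, 14111 SMAD3 and 18780 SMAD4 peaks were left. The share of NFAT5 peaks overlapping all 3 SMADs was 81.2% when at least 50% of the shorter peak had to be covered, 66.5% for midpoints within 200 bp, 73.0% in the widest 50% of each list and 35.3% in lists of equal length. In the same order, the share overlapping any SMAD was 96.1%, 91.8%, 94.95% and 70.6%. Both kept their values on the autosomes alone, within the counting interval. With at least 50% of the shorter peak covered, NFAT5 overlapped SMAD2 at 90.3%, SMAD3 at 86.7% and SMAD4 at 91.2%, SMAD3 overlapped SMAD2 at 88.1% and SMAD4 at 82.0%, and SMAD4 overlapped SMAD2 at 83.8%. For midpoints within 200 bp these 6 shares were, in the same order, 81.8%, 78.3%, 80.9%, 83.5%, 75.7% and 78.6%. In the widest 50% they were 87.7%, 81.1%, 86.6%, 82.0%, 75.9% and 77.5%. In lists of equal length they were 52.5%, 53.0%, 52.4%, 67.2%, 65.3% and 66.2%. Of these shares, taken over the shorter list, only in that setting did all 3 pairs of SMADs exceed every pair with NFAT5. Taken over the SMAD lists, 23.1%, 29.3% and 27.0% of SMAD2, SMAD3 and SMAD4 peaks overlapped NFAT5 with the full lists.

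The share of peaks at gene ends was 45.4%, 36.9%, 40.4% and 39.8% within 3 kb for NFAT5, SMAD2, SMAD3 and SMAD4. With coding genes alone it was 27.9%, 20.3%, 23.7% and 23.6%. In the widest 50% it was 29.8% for SMAD2, 34.2% for SMAD3 and 35.3% for SMAD4, and 34.3% for NFAT5, which was then no longer the highest. Genes with all 4 libraries numbered 2393 within 1 kb, 6988 within 20 kb and 1654 in the widest 50%. They numbered 5120 with the gene span plus 5 kb. Genes near an NFAT5 peak that itself overlapped all 3 SMADs numbered 3455, counted whether or not the SMAD midpoints lay within 5 kb. Within 1 kb, 4 TGFβ/SMAD target genes had NFAT5 and 4 had all 4 libraries. Osmotic-stress genes with all 4 libraries numbered 3 within 1 kb, 8 within 20 kb and 3 in the widest 50%, while their NFAT5 count of 5 to 9 lay at percentiles of 98.0 to 99.9 in all 4 settings.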

Other observations

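The tests of chance overlap, of a shared preference for gene ends, of the osmotic-stress widths, of a missing control library, of sites far from genes and of the S100 cluster were chosen only after the result was seen, although the placements used for the first 2 were planned before the data were examined. Regions bound by different combinations of SMADs lay at different places. Of the 945 regions with SMAD3 and SMAD4 and no SMAD2 or NFAT5, 44.9% (41.7 to 48.1) lay within 1 kb of a coding gene end. The share was 11.5% (10.7 to 12.3) for 6531 regions with SMAD2 alone, 15.9% (14.5 to 17.3) for SMAD2 with SMAD3, and 21.3% (20.6 to 22.0) for the 3 SMADs together. In between or close by were SMAD2 with SMAD4 at 18.9% (17.8 to 20.1), SMAD4 alone at 23.5% (22.0 to 24.9) and SMAD3 alone at 24.7% (22.6 to 26.8). With NFAT5 added the order was partly different. The share was 65.1% (56.7 to 72.8) of 146 regions with NFAT5, SMAD3 and SMAD4, and 53.3% (37.9 to 68.3) of 45 with NFAT5 and SMAD3. It was 47.6% (39.9 to 55.4) of 170 with NFAT5, SMAD2 and SMAD3, and 37.2% (32.4 to 42.2) of 392 with NFAT5, SMAD2 and SMAD4. It was 36.5% (29.0 to 44.6) of 156 with NFAT5 and SMAD4, 32.7% (24.2 to 42.2) of 113 with NFAT5 and SMAD2, and 25.9% (24.9 to 26.9) of 7719 regions with all 4.

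Near their ends, the osmotic-stress genes also tended to have NFAT5 peaks that were wide for the SMAD4 peaks beside them. The log2 ratio of the widest NFAT5 to the widest SMAD4 peak within 5 kb of a gene's ends had a median of -0.65 over 4180 genes with both. It was 1.11 at Slc5a3, 0.72 at Slc6a6, 0.34 at Slc38a2, -0.08 at Hspa1b, -0.50 at Nfat5 and -1.98 at Hspa4l. The other NFAT5 peaks in the span of Slc6a6, farther from its ends, each lay inside a wider SMAD4 peak. For 10 TGFβ/SMAD target genes the median was -0.98, at percentile 8.8 of random lists against SMAD4; against SMAD3 it lay at 24.7 and against SMAD2 at 67.8, all within the central 95%.

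Nearly every NFAT5 peak lay at a SMAD peak, and 3 technical explanations were weighed. Chance overlap of long lists would have given at most 1.04% of NFAT5 peaks at all 3 SMADs, against 84.4% observed. A common preference for gene ends, drawn at random from all coding gene ends of the chromosome, would have given at most 4.24%. These placements cannot say what a shared preference for certain gene ends would give. The same open chromatin recovered by every antibody would leave NFAT5 no wider, relative to the SMADs, at its known targets. The width ratio cannot decide this by itself. It took each library's widest peak within 5 kb of a gene's ends, whether or not the peaks overlapped. At Slc6a6 the NFAT5 peak did not overlap the SMAD2 peak it was set against. The median width ratio of the osmotic-stress genes lay at percentile 99.8 of random lists against SMAD4, 99.7 against SMAD2 but 94.0 against SMAD3. With the most influential gene left out, it lay at 97.2 against SMAD4 and 97.5 against SMAD2 (without Slc38a2). Against SMAD3 it then lay at 85.9 (without Slc6a6). Other lists were as far out against SMAD3, with the AP-1 genes also at 94.0 and the MAPK output genes at 1.5. The ratio was looked at in 11 gene lists, and SMAD4 alone was to decide until the SMAD3 value was seen; with all 3 SMADs needed, for these genes open chromatin cannot be told apart from NFAT5 binding. For the other sites it stays open as well, since 42.9% of the housekeeping genes had all 4 libraries and no control library was analysed here; no biological explanation was tested.

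The share of SMAD sites with NFAT5 differed between chromosomes, and sites within 5 kb of a gene end do not alone account for it. At 14123 sites over 5 kb from any coding gene end the autosomes still spanned 20.2 percentage points. They ran from 20.9% on chromosome 14 to 41.1% on chromosome 19, and the widest span in 1000 reassignments of NFAT5 among sites was 11.8. Distance beyond 5 kb was not matched, so an effect of it stays open. The reassignments also treated neighbouring sites as independent, which can make their span too narrow. The reassignments were not matched on peak width. Among the autosomes the median width of these sites ran from 460 bp on chromosomes 4 and 14 to 520 bp on chromosome 19. It was 500 bp on chromosome 18, where the NFAT5 share at these sites was 27.0%. A relation with width was not tested. A candidate explanation is DNA copy number of whole chromosomes in this cancer line, which would move the detection of weak sites in every library. Over the 19 autosomes, the share of gene-distal SMAD2 peaks that overlapped SMAD3, from 61.4% on chromosome 10 to 71.5% on chromosome 17, rose with the NFAT5 share (Pearson's r = 0.88, Spearman's rho = 0.85, permutation p = 2e-05 for both, the smallest they can give, adjusted 6e-05 over 3 relations; r = 0.86 without chromosomes 10 and 14). The NFAT5 shares at gene-distal sites in the lower- and the higher-coordinate part of each chromosome also went together (r = 0.79, permutation p = 0.00018, adjusted 0.00027; rho = 0.69, permutation p = 0.00174, adjusted 0.00261; r = 0.75 without chromosomes 8 and 10), and the relation with coding genes per Mb was weaker (r = 0.47, permutation p = 0.0305, adjusted 0.0305; rho = 0.38, permutation p = 0.114, adjusted 0.114; r = 0.49 without chromosomes 10 and 14). No DNA copy number was measured in these files, other differences between whole chromosomes stay open, and no biological explanation was tested.

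The many S100 genes with NFAT5 may reflect their place in the genome. The cluster from S100a1 to S100a9 on chromosome 3 (90511034 to 90695721) held 12 neighbouring coding genes, 8 of them with NFAT5. This count took every coding gene of the run, all 12 of them S100a genes by name, whether in the S100 list or not. It therefore need not hold the same genes as the 8 bound list members on chromosome 3. Neighbouring genes can count the same peaks, most of all in a cluster as dense as this one. Among 5044 runs of 12 neighbouring coding genes with 1/2 to 2 times its length of 184.7 kb, 8 lay at percentile 94.0. The cluster to S100a6 alone (9 genes, 8 with NFAT5), which was tried first and leaves out members without NFAT5, lay at 98.6 of its own runs, so the sharing of peaks cannot be told apart from preferential binding, because the result turns on where the cluster ends. Against runs of any length, tried before, the longer cluster lay at 97.8 and the shorter at 99.6. S100 was also the list with the highest NFAT5 share of 15. Among the 189 runs of like length on chromosome 3 the longer cluster lay at percentile 56.6 and the shorter, among 125, at 87.6. Against chromosome 3 runs of any length the longer cluster lay at 88.2 and the shorter at 97.1. All these runs overlapped one another and included the cluster itself, which draws its percentile toward the middle. The high NFAT5 share of the whole chromosome is therefore a candidate explanation that the data leave open. No biological explanation was tested.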
